A study of Mus musculus with 64 samples.

How the data were processed

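Gene expression was measured on Agilent arrays with a pair of dyes in the Harderian gland, a lipid-secreting gland behind the mouse eye, and in skin. The mice were wild type or carried a knockout of the aldehyde oxidase gene that the labels call Aoh2, whose current symbol is Aox4. Each array carried RNA of a knockout mouse in 1 dye and of a wild-type mouse of the same sex in the other. In the Harderian gland every pair of mice was hybridised on a second array with the dyes exchanged. The series holds 64 samples, which are 60 Harderian gland channels on 30 arrays (30 mice in 15 pairs) and 4 skin arrays (8 mice in 4 pairs). The deposited scanner values of each Harderian gland array were stored under both of its channels, and the copies were identical for all 30 arrays.

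Per the file headers, the deposited scanner values are mean spot intensities and median local background intensities written by Feature Extraction 9.1.3.1, and the processed signals beside them were background-adjusted and dye-normalised by the same software. Per the labels, RNA was extracted with a column kit and labelled through amino allyl nucleotides, and the authors normalised the Harderian gland channels with vsn. Per the labels, the authors excluded 6 channels on 5 arrays for quality reasons. The deposited Harderian gland table holds 54 channels on a natural log scale, which was read from the values: the slope of each column on the natural log of its own channel's signal was 1.03 to 1.22 (r 0.994 to 1.00, across probes). The deposited skin values are the log2 ratio of labelled knockout over labelled wild type, with slopes of 0.954 to 0.971 on the log2 ratio of the scanner values where the knockout carried Cy5 and of -0.975 to -0.907 where it carried Cy3. The constants of the vsn fit, the RNA quality and the position of the Aox4 probe relative to the deleted part of the gene are not given in the sources used here.

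The arrays without an excluded channel were used, which left 25 Harderian gland arrays and 14 pairs (28 mice), with 5 pairs of young males and 3 pairs each of young females, adult males and adult females. Of these pairs 11 had both arrays and 3 had 1 array. All 4 skin pairs were used. Computations ran in R 4.3.3 with limma 3.58.1, the data.table package at 1.17.8 and statmod 1.5.0. Spots marked as outliers by Feature Extraction were left out, the background was corrected with normexp and an offset of 50, dyes were balanced within each array by loess, and arrays were put on a common mean intensity by Aquantile. A gene's dye effect, estimated from the pairs with both dye orders, was subtracted in the Harderian gland, and the arrays of a pair of mice were averaged. A probe was tested if it was well above background in at least 50% of the wild-type or of the knockout channels of any of the 4 groups, which 36455 of 41174 probes were in the Harderian gland and 27138 in skin. The probe with the highest mean intensity stood for a gene. Of the probes on the Harderian gland array, 22864 were named by their accession, 10230 by symbol or synonym, and 8080 had no current symbol (8072 on the skin array). Names came from the annotation of assembly GRCm38.p6. Since the array files name no build, that annotation was used only for names and for which genes lie near Aox4. Probe sequences were not matched to the genome. This left 24470 genes in the Harderian gland and 18315 in skin.

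Knockout and wild type were compared through the log2 ratio within each pair, with limma's moderated test on the 4 Harderian gland groups together, so that the spread was pooled over all pairs. The contrasts were the mean of the 4 groups with equal weight, each group, and the genotype effect by age and by sex. Wild-type mice were compared between sexes and ages through their log2 intensities. Skin was a separate fit. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method across genes within each comparison, with a threshold of 0.05. The pairing was checked through the deviations of each mouse from the mean of its group and genotype. Across genes, the deviations of a pair's wild type and knockout correlated at 0.443 to 0.887 in the 14 Harderian gland pairs, and at 0.486, 0.227, -0.117 and 0.319 in the skin pairs, and genes are not independent replicates. The 2 mice of a pair shared their arrays, so a shared array and a shared origin both enter that value. With no replicate block, which treats the mice of a pair as unrelated, 4 genes passed over all groups in place of 14, and in young males 0 in place of 205 (336 at an unadjusted p under 0.05). Across genes, the log2 ratios of a pair's exchanged dye orders correlated at a median of 0.699 (0.400 to 0.899). Scan dates gave 10 blocks among the Harderian gland pairs. No date held 2 or more mice of each of 2 groups, so within-date values could not be had, and scan date was tried as a random block. In skin all arrays were scanned on 1 date, and the dye order was also the slide.

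The comparisons, 35 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Aox4 in every comparison. Over all groups, in skin and between wild-type mice it names the 10 genes with the largest log2 fold change in each direction among those past the threshold with a current symbol and, for knockout against wild type, the same direction in every pair. In single groups and interactions it names 5 in each direction. Where fewer than 5 genes passed, the 5 with the smallest p are named as not past the threshold, and up to 4 members with the smallest p are named for a list. Some genes that the rule names are not reported here. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the residuals, and with fry, which asks whether the members move one way without comparing them with other genes. List tests ran on 24210 genes with complete values in the Harderian gland and 18000 in skin, and a list needed 5 measured members. With the estimated correlation, 0 of the 35 lists passed in each of the 13 comparisons. Genes near Aox4 were counted within 5 Mb, and within 10 and 20 Mb as alternatives. Nearness to Aox4 and the lists used Fisher's exact test and limma, and single values used exact sign or permutation tests.

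The gene test was tried on simulated arrays with the real dye effect, spread, brightness and missing spots and with genes drawn independently, and known changes were planted in up to 67 genes at each of 3 sizes per comparison. Over all groups, with 24470 genes run, 98.5% of planted log2 changes of 0.5 were recovered and 100% of changes of 1. For a change of 1 the recovery was 100% in young males, young females and adult females and 98.5% in adult males. It was 95.5% for the genotype effect by age and 100% by sex. In wild-type mice it was 37.3% between sexes when young and 29.2% when adult, 51.6% between ages in males, 31.3% in females and 5.97% for sex by age, and for a change of 2 these recoveries were 95.4%, 96.9%, 98.4%, 100% and 84.6%. In skin, with 18315 genes run, it was 8.96% for a change of 1 and 74.2% for a change of 2. The planted changes of a comparison were tested together, so their many calls eased its adjusted threshold. The adult male run gave 249 calls and the adult female run 243, where the real data gave 1 each. By age and by sex the runs gave 231 and 245, against 0. These rates may therefore be too high where few genes changed, and they do not show that changes of that size were absent. A list planted with a log2 change of 0.5 was called in each of the 13 comparisons. In the Harderian gland knockout comparisons and interactions 1 to 3 other lists passed with it, all of which share members with the planted list, and 0 passed elsewhere. Since genes were drawn independently, the members of a list did not move together in these runs. They therefore do not show how often camera calls a list falsely in the real data.

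The alternatives were no probe filter, stricter probe filters, every probe, no background subtraction, the Feature Extraction processed signals, median centring, quantile normalisation, no dye correction, outlier spots kept, all 30 arrays, a different prior, array weights, the authors' deposited values, groups fitted on their own pairs, no replicate block, scan date as a block, all mice with the pair as a block, and each pair left out. Alternatives added after the data were seen were a filter set 2 median absolute deviations above the negative controls, leaving out a young male array with scattered negative controls, leaving out that array and the young male pair with the widest log ratios, and reading the neighbours of Aox4 in skin on the probe used in the gland, since each tissue otherwise used its own brightest probe of a gene. The median net signal of the Harderian gland arrays was 66.3 to 178 in green and 44.1 to 104 in red, and 63.2% to 90.3% of probes per array were well above background. In skin these values were 57.9 to 100.1, 83.2 to 190.3 and 55.0% to 68.8%. The number of arrays limits the precision of every value. The vsn package was not used.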

Results

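The data are log2 intensities and log2 knockout over wild-type ratios from 25 Harderian gland arrays (14 pairs of mice) and 4 skin arrays (4 pairs). The Harderian gland pairs were 5 of young males and 3 of young females, both aged 5 to 6 weeks, and 3 of adult males and 3 of adult females, both aged 8 to 9 weeks. The skin mice were adult females of 8 weeks. Medians of net signal per array lay between 66.3 and 178 in green and between 44.1 and 104 in red in the Harderian gland, and between 57.9 and 100.1 and between 83.2 and 190.3 in skin. The Y-linked genes separated the labelled sexes in all 28 Harderian gland mice. Ddx3y read 9.18 to 9.70 on the log2 scale in 16 males and 6.04 to 6.26 in 12 females. Kdm5d read 7.73 to 8.54 and 6.34 to 6.47.

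The first comparison asked what the loss of Aox4, an aldehyde oxidase that the series title links to retinoic acid synthesis, changes in the Harderian gland over both sexes and ages. Aox4 itself was lower in the knockout in 14 of 14 pairs and on 30 of 30 arrays, by -3.18 on the log2 scale (SE 0.107, adjusted p = 4.86e-09), a 9.05-fold difference. Its mean log2 intensity was 13.34 (SD 0.74, n = 14) in wild type and 10.23 (SD 0.80, n = 14) in knockout, and the knockout channels were still above background. The pair values ran from -4.67 to -2.43 (mean -3.11, SD 0.60, n = 14; exact two-sided sign test p = 0.000122, the smallest that 14 pairs allow). In the skin the direction was the opposite of the labels, as given further on.

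**Figure D1:**
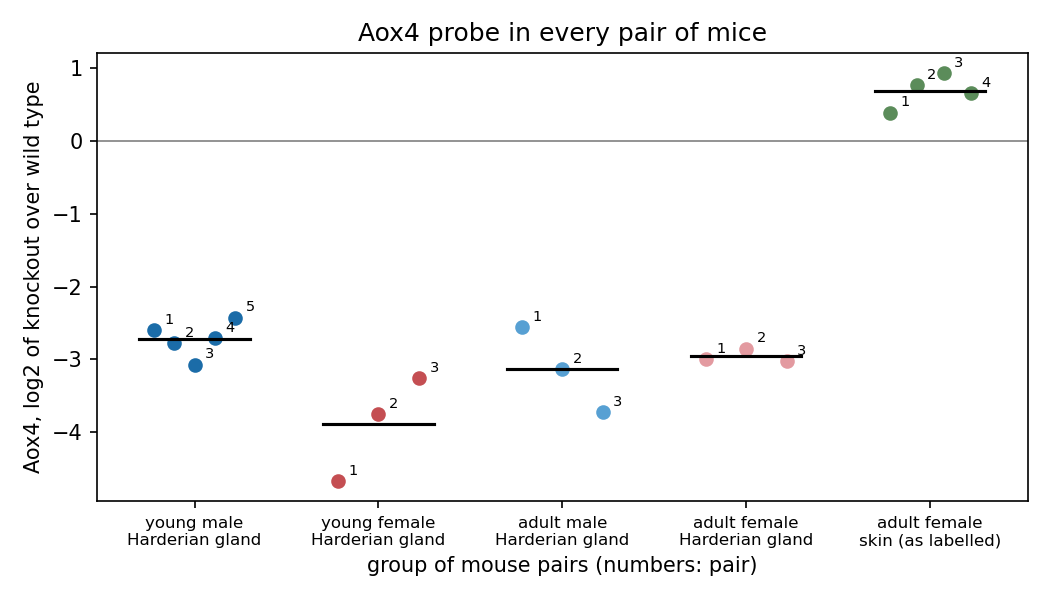
Log2 ratio of Aox4 in knockout over wild type (y axis) for each pair of mice (points) in the 4 Harderian gland groups and in skin as labelled, with the mean of each group as a black line. The 14 Harderian gland pairs lie between -4.67 and -2.43 and the 4 skin pairs between 0.39 and 0.93.

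Past Aox4, few genes changed over all groups, and most of the named ones are its neighbours on chromosome 1. Map2, a microtubule-associated protein, fell by 0.81 on the log2 scale (SE 0.0587, adjusted p = 3.95e-05), in 14 of 14 pairs. That value rests on 1 probe. Dimmer probes of Map2, above background in 46% to 76% of channels, had means of 0.025, -0.029 and -0.049 over the pairs. Bzw1, a regulator of translation, rose by 0.47 (SE 0.0457, adjusted p = 0.000667), the peptidyl-prolyl isomerase Ppil3 by 0.36 (SE 0.0418, adjusted p = 0.00333) and Ubxn2a, which lies on chromosome 12, by 0.28 (SE 0.0284, adjusted p = 0.00103), each in 14 of 14 pairs. Mfsd9 (0.84, SE 0.0987, higher in 13 of 14 pairs), the interleukin receptor Il1r1 (-0.38, SE 0.0443, lower in 13) and the iron exporter Slc40a1 (-0.24, SE 0.0384, lower in 13) passed as well, at adjusted p = 0.00333, 0.00333 and 0.0464. They were named only after their values were seen, since 1 pair went the other way. In all 14 of 24470 genes passed, 8 higher and 6 lower, and 12 of them had a current symbol, while 3410 had an unadjusted p under 0.05. Within 20 Mb of Aox4, 7 of 228 other genes passed against 6 of 24241 elsewhere (odds ratio 127, Fisher's exact two-sided p = 9.1e-12). Within 5 Mb it was 2 of 68 against 11 of 24401 (odds ratio 67.0, p = 0.000582). Treating the mice of a pair as unrelated left 4 genes and ended the calls of Bzw1, Ppil3 and Ubxn2a (adjusted p = 0.126, 0.662 and 1.00). Aox4 and Map2 passed in all 31 alternatives run. The count was 193 without pair 5 of the young males, 9 without their pair 1, 30 without pair 3 of the young females, 8 without pair 3 of the adult males and 9 without pair 2 of the adult females. It was 34 when every probe was tested, 35 with array weights, 8 with scan date as a block and 33 without the young male array with scattered controls and the pair with the widest log ratios.

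Of the lists tied to the purpose of the study, the direct targets of retinoic acid leaned lower. Of these, 45 of 64 measured members were negative and 19 positive (median log2 ratio -0.016), at adjusted p = 0.0209 by camera and adjusted p = 0.863 with an estimated correlation. When adjusted over the list alone, 4 members passed and over all genes 0. These were Cpt1a, which carries fatty acids into mitochondria (-0.17, SE 0.0345), Meis1 (-0.097, SE 0.0261), Egr1 (-0.33, SE 0.0905) and the transcription factor Cebpb (0.10, SE 0.0256). The median of the list was negative in 12 of 14 pairs (mean of the pair medians -0.022, SD 0.030). Retinoid metabolism and transport showed no shift, with 22 members positive and 21 negative of 43 (median 0.0038, adjusted p = 0.753). Adh5 (0.084, SE 0.0257) and Dhrs9 (0.14, SE 0.0452) had its smallest p (adjusted p = 0.177 and 0.182). Retinoid receptors and their partners gave adjusted p = 0.434. The molybdenum flavoenzymes, the family of Aox4, had a median of 0.0039 but a mean of -0.26 carried by Aox4. Camera, which read lower, gave adjusted p = 0.308 while fry gave 0.000442. No other member of that list passed over all genes or adjusted over the list alone. Mocs1 was at -0.072 (SE 0.0283), Mocos at -0.11 (SE 0.0493) and the paralog Aox3 at 0.16 (SE 0.0722).

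Lipid and stress lists also moved over all groups. Fatty acid oxidation and PPAR targets were lower, with 30 of 38 members negative (median -0.053, turning to 0.028 under median centring), at adjusted p = 0.00156 and adjusted p = 0.863 with an estimated correlation. Of its members 4 passed when adjusted over the list alone, among them Cpt1a and the beta oxidation enzyme Hadha (-0.14, SE 0.0292) as lower and the carnitine carrier Slc25a20 (0.16, SE 0.0446) as higher. Endoplasmic reticulum stress genes leaned higher, with 21 of 30 positive (median 0.066, adjusted p = 0.0290, and adjusted p = 0.863 with an estimated correlation). Dnajc3, a chaperone of that compartment, passed when adjusted over the list alone (0.19, SE 0.0370). Immediate early genes, which respond within minutes to stimulation, leaned lower with 16 of 22 negative (median -0.061, adjusted p = 0.0195, and adjusted p = 0.863 with an estimated correlation). Zfp36 (-0.25, SE 0.0515), Egr1 (-0.33, SE 0.0905) and Dusp1 (-0.32, SE 0.0901) passed when adjusted over the list alone. Cholesterol synthesis did not pass (median -0.022, adjusted p = 0.526), though 4 members passed when adjusted over the list alone: Hmgcs1 (-0.27, SE 0.0687), Sqle (-0.099, SE 0.0273) and Tm7sf2 (-0.099, SE 0.0242) lower and Nsdhl (0.13, SE 0.0378) higher. Of all 35 lists 9 passed by camera, 2 higher and 7 lower, 0 with an estimated correlation and 1 by fry. The 1 by fry was the molybdenum list with Aox4 in it, which is not among the 9.

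Markers of other tissues moved in the same comparison. Muscle genes were lower, with 33 of 34 negative (median -0.29, adjusted p = 0.00156, and adjusted p = 0.873 with an estimated correlation), but the list's median over pairs ran from -1.58 to 1.42 and was positive in 4 of 14 pairs. Myh2, a myosin of fast fibres, read -0.74 (SE 0.393) and Actn2 -0.41 (SE 0.272). Proliferation genes were higher, with 26 of 33 positive (median 0.071, adjusted p = 0.0209, and adjusted p = 0.873 with an estimated correlation), but their pair medians ran from -0.24 to 0.52 and were negative in 8 of 14 pairs. Fibroblast and extracellular matrix genes were lower, with 21 of 23 negative (median -0.061, adjusted p = 0.0300, and adjusted p = 0.873 with an estimated correlation), for example Loxl1 (-0.17, SE 0.0566) and Col3a1 (-0.26, SE 0.114), but the pair medians were positive in 7 and negative in 7 pairs (-0.62 to 0.28). Basal keratinocyte genes (15 of 19 negative, median -0.050, adjusted p = 0.0184) and cornified envelope genes (22 of 29 negative, median -0.045, adjusted p = 0.0138) were lower as well, each at adjusted p = 0.863 with an estimated correlation. Krt15, a basal keratin, read -0.50 (SE 0.198) and Asprv1 -0.40 (SE 0.140). Adjusted over the list alone, 0 members of these 5 lists passed by limma.

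**Figure D2:**
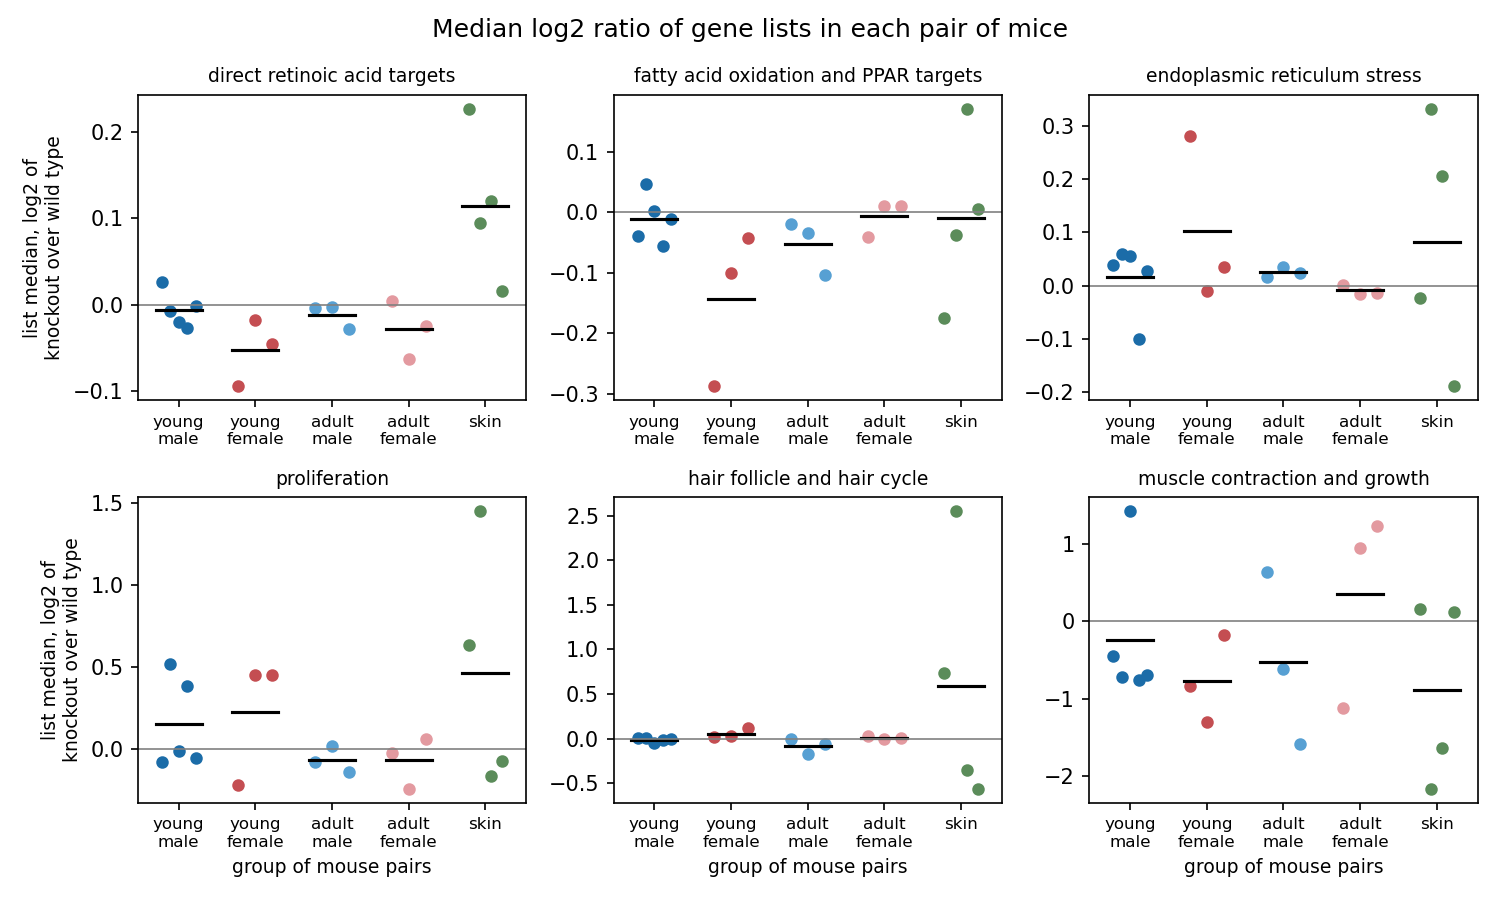
Median log2 ratio of knockout over wild type (y axis) of 6 gene lists for each pair (points) by Harderian gland group and in skin as labelled, with group means as black lines. The medians of direct retinoic acid targets are negative in 12 of 14 Harderian gland pairs, while those of the muscle list run from -1.58 to 1.42; the fatty acid oxidation list turns from -0.053 to 0.028 over all groups under median centring.

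The knockout was next compared with wild type in young males (5 pairs). Aox4 fell by 2.72 on the log2 scale (SE 0.174, adjusted p = 1.86e-05, 6.58-fold, lower in 5 of 5 pairs). Map2 (-0.66, SE 0.0959) and Il1r1 (-0.47, SE 0.0724) fell with it, at adjusted p = 0.0119 and 0.0130. The potassium channel Kcna7 fell by 0.18 (SE 0.0346, adjusted p = 0.0300). Higher in 5 of 5 pairs were the Myc family gene Mycl (1.33, SE 0.230, adjusted p = 0.0214), the muscle ubiquitin ligase Trim63 (1.29, SE 0.232, adjusted p = 0.0255) and the sarcomere protein Mypn (1.29, SE 0.246, adjusted p = 0.0305). So were the G protein subunit Gnai1 (1.26, SE 0.25, adjusted p = 0.0357) and the blood cell transcription factor Tal1 (1.26, SE 0.233, adjusted p = 0.0295). Each of these values rests on 1 probe, and dimmer probes of the same genes read lower over these pairs, with means of -0.069 for Trim63, -0.022 for Mypn, and -0.086, 0.050 and 0.33 for Gnai1. The muscle list as a whole did not rise with Trim63 and Mypn in every pair: its median was 1.42 in pair 3 and -0.75 to -0.44 in the others. In all 205 genes passed, 195 higher and 10 lower (3241 at an unadjusted p under 0.05), and 110 had a current symbol. Zinc finger genes made up 27 of the 195 higher genes (13.9%) against 337 of 24470 tested (1.38%), a count made after the genes were seen and not tested, since these genes move together. Zfp119b (0.66, SE 0.0701) and Zfp932 (0.87, SE 0.123) had the smallest p among them (adjusted p = 0.00714 and 0.0119).

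The higher genes of young males moved together from pair to pair. The median of those 195 genes was 0.81, 0.85, 1.00, 0.85 and 0.20 in the 5 young male pairs. It was also 0.90 and 0.53 in 2 of the 3 adult male pairs, between 0.05 and 0.30 in young females and between -0.38 and -0.08 in adult females. Retinoid metabolism and transport passed by camera and by fry, with 31 of 43 members positive (median 0.042, camera adjusted p = 0.0300, fry adjusted p = 0.0444, and adjusted p = 0.815 with an estimated correlation). Its Adh5, an alcohol dehydrogenase, passed over all genes (0.23, SE 0.0420, adjusted p = 0.0277). In that list 6 members passed when adjusted over the list alone, among them Dhrs9 (0.33, SE 0.0737), the fatty acid binding Fabp5 (0.51, SE 0.115) and the retinol carrier Rbp4 (0.16, SE 0.0483). Proliferation was higher (31 of 33 positive, median 0.13, adjusted p = 0.0105, and adjusted p = 0.886 with an estimated correlation), with Top2a at 0.29 (SE 0.115), but its pair medians were positive in 2 of 5 pairs (-0.077 to 0.52). Extracellular matrix was higher too, against its direction over all groups (20 of 23 positive, median 0.16, adjusted p = 0.0105, and adjusted p = 0.886 with an estimated correlation), with Vim at 0.36 (SE 0.127). Interferon response genes were higher (23 of 26 positive, median 0.067, adjusted p = 0.0351, and adjusted p = 0.886 with an estimated correlation), with Ifi47 at 0.25 (SE 0.127), but their pair medians were positive in 3 of 5 pairs and 0.45 in pair 2 against -0.011 to 0.043 in the others. Immune cell genes were higher (23 of 31 positive, median 0.037, adjusted p = 0.0376, and adjusted p = 0.865 with an estimated correlation), though their median turned to -0.0098 without the dye correction. The macrophage marker Adgre1 read 0.23 (SE 0.0597). Cornified envelope genes were lower (20 of 29 negative, median -0.064, adjusted p = 0.0345, and adjusted p = 0.865 with an estimated correlation), with Cdsn at -0.16 (SE 0.0456). The gene count fell to 1 without pair 4, 2 without pair 2, and 3 without pair 1 or without pair 3. It was 3 when the group was fitted on its own pairs, 2 with the authors' deposited values and 0 with no replicate block (336 at an unadjusted p under 0.05), where Aox4 had adjusted p = 0.0883. It was 354 without pair 5, 84 without pair 3 of the adult males, and 105 and 122 without pairs 2 and 3 of the adult females. It was 564 without the dye correction, 108 without background subtraction, 121 with a robust prior and 95 with array weights.

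**Figure D3:**
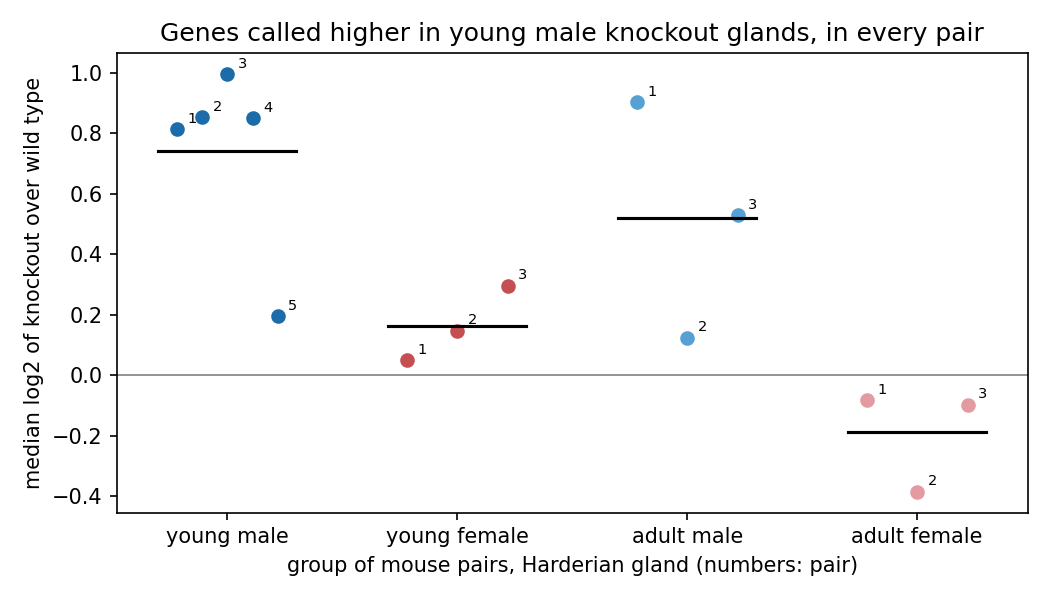
Median log2 ratio of knockout over wild type (y axis) of the 195 genes that passed as higher in young males, for each pair (points) by Harderian gland group, with group means as black lines. Since the genes were chosen in young males, the 5 pairs of that group are high by choice, and the adult female pairs lie between -0.38 and -0.08.

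In young females (3 pairs), where 250 genes passed, Aox4 fell by 3.89 on the log2 scale (SE 0.225, adjusted p = 5.04e-06, 14.9-fold, lower in 3 of 3 pairs) and Map2 by 1.00 (SE 0.124, adjusted p = 0.0105). Spc25, a kinetochore protein, rose by 1.17 (SE 0.163, adjusted p = 0.0210), the peptide-amidating enzyme Pam by 1.32 (SE 0.270, adjusted p = 0.0467) and the growth cone protein Basp1 by 1.46 (SE 0.302, adjusted p = 0.0478), in 3 of 3 pairs each. So did Mlec, a lectin of the endoplasmic reticulum, by 1.04 (SE 0.221, adjusted p = 0.0479) and D17H6S56E-5 by 1.07 (SE 0.166, adjusted p = 0.0266). Micall2 (-0.80, SE 0.170), Plekha6 (-0.78, SE 0.167) and the RNA-binding Pcbp2 (-0.70, SE 0.140) fell in 3 of 3 pairs, at adjusted p = 0.0479, 0.0479 and 0.0463. The paralog Aox1 fell by 0.28 (SE 0.0602, adjusted p = 0.0485), and it was named after its value was seen. Over all 14 pairs its probe, without the dye correction, had a mean of -0.064 (SD 0.165) and was positive in 5. Of the 250 genes 135 were higher and 115 lower (4338 at an unadjusted p under 0.05), and 201 had a current symbol. Young males and young females shared 11 higher genes and 6 lower ones, among the latter Aox4, Hexdc, Il1r1, Map2 and Prmt1. Independent lists would share 1.08 and 0.047. Both groups were tested with the same pooled spread and dye correction of each gene, so their lists are not independent and these values do not measure chance.

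Fatty acid oxidation and PPAR targets were lower in young females, with 28 of 38 negative (median -0.14, adjusted p = 0.000472, and adjusted p = 0.679 with an estimated correlation). Cpt1a passed over all genes (-0.35, SE 0.0727, adjusted p = 0.0478). With adjustment over the list alone 8 members passed as lower, with Hadha at -0.28 (SE 0.0616), and 2 as higher, with Slc25a20 at 0.47 (SE 0.106). Direct retinoic acid targets were lower (49 of 64 negative, median -0.046, adjusted p = 0.0394, and adjusted p = 0.679 with an estimated correlation). There Cpt1a, Meis1 (-0.22, SE 0.0550) and Egr1 (-0.73, SE 0.191) passed when adjusted over the list alone. Endoplasmic reticulum stress genes were higher (20 of 30 positive, median 0.11, adjusted p = 0.0257, and adjusted p = 0.679 with an estimated correlation). Of these 4 passed when adjusted over the list alone: Manf (0.41, SE 0.108), Dnajc3 (0.29, SE 0.0779), the unfolded protein response regulator Xbp1 (0.55, SE 0.169) and the chaperone Hspa5 (0.43, SE 0.132). Immediate early genes were lower (16 of 22 negative, median -0.13, adjusted p = 0.0494, and adjusted p = 0.679 with an estimated correlation). Zfp36 passed over all genes (-0.52, SE 0.108, adjusted p = 0.0478) and 5 passed when adjusted over the list alone, 4 of them lower, with Jun at -0.88 (SE 0.226) and Jund at -0.44 (SE 0.107). Proliferation was higher (28 of 33 positive, median 0.23, adjusted p = 6.91e-05) and muscle lower (32 of 34 negative, median -0.75, adjusted p = 4.82e-05), both at adjusted p = 0.679 with an estimated correlation. Extracellular matrix (21 of 23 negative, median -0.16, adjusted p = 0.00761), basal keratinocyte (15 of 19 negative, median -0.13, adjusted p = 0.0257) and interferon response genes (25 of 26 negative, median -0.092, adjusted p = 0.0286) were lower, each at adjusted p = 0.679 with an estimated correlation. The pair medians of the proliferation (-0.22 to 0.45), extracellular matrix (-0.62 to 0.28), basal keratinocyte, immediate early and endoplasmic reticulum stress lists went these ways in 2 of 3 pairs, and those of the other lists in 3 of 3. Tyms read 0.38 (SE 0.0859), Myh1 -1.99 (SE 0.952), Krt5 -0.63 (SE 0.260) and Irf1 -0.36 (SE 0.119). The gene count was 3 without pair 1 and 1331 without pair 3, 762 and 407 without young male pairs 2 and 3, and 93 without adult male pair 3. It was 22 to 37 without pair 2, young male pair 1 or 5, adult male pair 1 or 2 or any adult female pair. It was 22 with scan date as a block, 6 under median centring, 3 with the authors' deposited values, 1 with the Feature Extraction signals and 1 with no replicate block. It was 0 when fitted on its own pairs (2864 at an unadjusted p under 0.05), where Aox4 had adjusted p = 0.308. With every probe tested 1050 probes passed, and the count was 752 genes without the young male array and pair named above, 728 with a strict filter and 518 with all 30 arrays. It was 138 without a filter, 148 without background subtraction, 83 without the dye correction and 155 with a robust prior.

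In adult males (3 pairs) and adult females (3 pairs) Aox4 was the single gene past the threshold. It fell by 3.14 (SE 0.225, adjusted p = 7.38e-05, 8.82-fold) in adult males and by 2.96 (SE 0.225, adjusted p = 0.000154, 7.77-fold) in adult females, in 3 of 3 pairs each. Its neighbour Map2 was at -0.75 (SE 0.124, adjusted p = 0.369) and -0.84 (SE 0.124, adjusted p = 0.143). Next in adult males were Mfsd9 (1.13, SE 0.208), Lrrc23 (-0.40, SE 0.0713) and the NF-kappa-B subunit Nfkb1 (0.32, SE 0.0597), all at adjusted p = 0.369. In adult females Dach1 (-0.32, SE 0.0667) and Cd164 (-0.21, SE 0.0420) were both at adjusted p = 1.00. At an unadjusted p under 0.05 there were 2056 genes in adult males and 575 in adult females. Map2 passed in adult females in 5 of 32 alternatives, among them all 30 arrays (adjusted p = 0.00799) and without young male pair 3 (0.0213) or young female pair 1 (0.0276). Mfsd9 passed in adult males without young female pair 3 (0.0296). In adult males the call of Aox4 itself ended when the group was fitted on its own pairs (adjusted p = 0.187) and with no replicate block (adjusted p = 0.409), which also ended it in adult females (adjusted p = 0.885).

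The gene lists of the adult groups went different ways. In adult males the hair follicle list was lower (26 of 32 negative, median -0.14, adjusted p = 1.19e-07, and adjusted p = 0.488 with an estimated correlation), with the hair proteins Krtap3-2 at -1.03 (SE 0.370) and Krtap8-1 at -1.45 (SE 0.540). Cornified envelope genes (24 of 29 negative, median -0.069, adjusted p = 0.000478), extracellular matrix (20 of 23 negative, median -0.18, adjusted p = 0.000478) and interferon response genes (23 of 26 negative, median -0.068, adjusted p = 0.00440) were lower, each at adjusted p = 0.747 with an estimated correlation. Dcn, a proteoglycan, read -0.29 (SE 0.12) and Psmb8 -0.33 (SE 0.145). Muscle genes were lower in adult males (32 of 34 negative, median -0.55, adjusted p = 0.00109, and adjusted p = 0.867 with an estimated correlation). They were higher in adult females (30 of 34 positive, median 0.39, adjusted p = 0.000419, and adjusted p = 0.983 with an estimated correlation). Their pair medians were 0.63, -0.62 and -1.58 in the males and -1.12, 0.94 and 1.23 in the females. Cholesterol synthesis genes were higher in adult females (18 of 24 positive, median 0.060, adjusted p = 0.00333, and adjusted p = 0.983 with an estimated correlation), with Mvd at 0.30 (SE 0.0822) and a positive median in 2 of 3 pairs. Adjusted over the list alone 0 members of these lists passed by limma.

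Whether the knockout effect differed by age or by sex was tested on the interaction terms. Aox4 differed by 0.26 (SE 0.214, adjusted p = 0.730) between adult and young pairs and by 0.50 (SE 0.214, adjusted p = 0.407) between male and female pairs. By age 0 of 24470 genes passed with limma (2438 at an unadjusted p under 0.05). The smallest p fell on Spc25 (-0.84, SE 0.155), Xiap (-0.47, SE 0.0888), Cdk18 (0.48, SE 0.0902), As3mt (-0.24, SE 0.0461, turning to 0.23 with the Feature Extraction signals) and Pds5a (-0.38, SE 0.0742), all at adjusted p = 0.356. By sex 0 passed with limma (2679 at an unadjusted p under 0.05). There 5730488B01Rik (1.45, SE 0.233), Atg4c (0.57, SE 0.0970), Nfkb1 (0.33, SE 0.0566), Adh5 (0.33, SE 0.0515) and Apool (0.26, SE 0.0396) came first at adjusted p = 0.115. In the retinoid metabolism list 5 members passed when adjusted over the list alone. Of these Adh5 (p = 0.00109), Aldh1a3, which makes retinoic acid (0.81, SE 0.198), Fabp5 (0.56, SE 0.141) and Dhrs9 (0.36, SE 0.0903) were higher in male than in female pairs. By age, proliferation (median -0.24, adjusted p = 2.28e-07) and hair follicle genes (median -0.11, adjusted p = 0.00661) were lower in the adult than in the young effect, both at adjusted p = 0.849 with an estimated correlation. Muscle (median 0.47, adjusted p = 0.00165) and adipocyte genes (median 0.20, adjusted p = 0.0407) were higher, both at adjusted p = 0.849 with an estimated correlation. Among them were Tyms (-0.28, SE 0.0815) and the fat cell hormone Adipoq (0.56, SE 0.232). By sex, hair follicle (median -0.13, adjusted p = 7.10e-05) and cornified envelope genes (median -0.040, adjusted p = 0.0362) were lower in the male than in the female effect, at adjusted p = 0.841 with an estimated correlation. Without pair 5 of the young males 188 genes passed by sex, the 5 named ones included.

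Wild-type mice were compared between the sexes at each age. In young mice (5 males, 3 females) the Y-linked genes Eif2s3y (3.59, SE 0.361, adjusted p = 0.00176) and Kdm5d (1.75, SE 0.133, adjusted p = 0.000104) were higher in males. So was Ddx3y, whose females were not above background, at least 10.1-fold (3.41, SE 0.0993, adjusted p = 1.26e-09). The sulfotransferase Sult1a1 was higher in young males by 1.07 (SE 0.142, adjusted p = 0.0279), a call that ended in 16 of 31 alternatives. The steroid-hydroxylating Cyp2b9 was next at 1.62 (SE 0.237, adjusted p = 0.0645). In adults (3 males, 3 females) Eif2s3y (3.61, SE 0.403, adjusted p = 0.00573), Ddx3y (at least 9.86-fold, 3.32, SE 0.111, adjusted p = 7.52e-09), Kdm5d (1.89, SE 0.149, adjusted p = 0.000155) and Uty (1.33, SE 0.174, adjusted p = 0.0229) were higher in males. Female channels were above background on 2 of 6 arrays in young and 3 of 6 in adult mice for Eif2s3y and on 2 of 6 for Uty, so the size of these differences depends on the background. Over the alternatives Eif2s3y ran from 3.19 to 6.76 in young and from 3.29 to 6.35 in adult mice, Uty from 1.07 to 3.69, and Kdm5d reached 3.37 and 3.77. Ddx3y ran from 2.949 to 6.908 in young and from 2.864 to 6.555 in adult mice, so its lower bounds hold for the main processing only. Chp1 missed the threshold (-0.66, SE 0.109, adjusted p = 0.197). Aox4 read -1.0 (SE 0.434, adjusted p = 0.634) in young and -0.44 (SE 0.485, adjusted p = 1.00) in adult males against females, and the young value was -0.58 without young male 4, whose level was far below the other males. At each age 4 genes passed, all higher in males (1890 and 749 at an unadjusted p under 0.05). In the adults 28 passed with array weights and 2 without male 1, which ended Eif2s3y and Uty (adjusted p = 0.0681 and 0.190). It was also 2 without female 2, where the same genes ended (adjusted p = 0.0517 and 0.181). With the filter that needs every channel well above background, which removes the Y-linked genes, 0 passed at either age (1348 and 419 at an unadjusted p under 0.05). In young mice 9 passed with every probe or with all mice and the pair as a block, and 7 without female 3.

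Among the lists, extracellular matrix genes were lower in young males than in young females (20 of 23 negative, median -0.31, adjusted p = 8.89e-06, and adjusted p = 0.630 with an estimated correlation). The proteoglycan Lum passed when adjusted over the list alone (-0.80, SE 0.180). Interferon response genes were lower in young males (21 of 26 negative, median -0.074, adjusted p = 0.0159, and adjusted p = 0.630 with an estimated correlation), with Oasl2 at -0.41 (SE 0.176). In adults basal keratinocyte (15 of 19 negative, median -0.14, adjusted p = 0.00594) and wounded epidermis genes (18 of 26 negative, median -0.095, adjusted p = 0.0266) were lower in males, each at adjusted p = 0.585 with an estimated correlation. Muscle genes were higher (30 of 34 positive, median 0.57, adjusted p = 0.000295, and adjusted p = 0.786 with an estimated correlation). Krt15 read -2.04 (SE 0.925), Egfr -0.25 (SE 0.0980) and Ckm 1.35 (SE 1.08). The list of sex chromosome genes passed at both ages: its median was 0.26 in young mice (adjusted p = 0.000537, and adjusted p = 0.0971 with an estimated correlation). In adults the median was -0.056, while the mean of 0.64 and the test pointed to males (adjusted p = 0.000178, and adjusted p = 0.0537 with an estimated correlation). It holds X-linked genes such as Eif2s3x, which was lower in young males when adjusted over the list alone (-0.51, SE 0.0842). Scan date was not fitted in the list tests between the sexes.

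Between ages, 7 lists passed by camera in wild-type mice of each sex, and 4 by fry in females. Scan date was not fitted in these list tests, and wild-type levels correlated at 0.447 within a scan date. Values within a date could not be had, so age and scan date cannot be fully told apart here. In females (3 adult, 3 young) 21 of 23 extracellular matrix genes were lower in adults (median -0.63, camera adjusted p = 2.63e-16, fry adjusted p = 0.0427, and adjusted p = 0.210 with an estimated correlation). Of them 13 passed when adjusted over the list alone, among them Col6a3 (-0.95, SE 0.173), Col6a1 (-0.81, SE 0.171), Loxl1 (-0.96, SE 0.201) and Thy1 (-0.83, SE 0.166). Myoepithelium and smooth muscle genes were lower in adult females (10 of 14 negative, median -0.22, adjusted p = 0.00730, fry adjusted p = 0.0427, and adjusted p = 0.226 with an estimated correlation). When adjusted over that list alone 4 passed: Cnn1 (-0.64, SE 0.147), Myl9 (-0.61, SE 0.144), Smtn (-0.60, SE 0.186) and Myh11 (-0.48, SE 0.163). Proliferation (median -0.24, adjusted p = 4.11e-06), interferon response (-0.12, adjusted p = 0.00730), immediate early (-0.18) and endothelium and blood genes (-0.17, adjusted p = 0.0290 for both) were lower in adult females, each at adjusted p = 0.717 with an estimated correlation. Cholesterol synthesis genes were lower too (median -0.10, adjusted p = 0.0290, and adjusted p = 0.481 with an estimated correlation). By fry alone fatty acid synthesis (fry adjusted p = 0.0427) and melanocyte genes (0.0497) passed as lower, at adjusted p = 0.584 and adjusted p = 0.481 with an estimated correlation. In males (3 adult, 5 young) 19 of 23 matrix genes were lower in adults (median -0.34, adjusted p = 9.42e-08, and adjusted p = 0.481 with an estimated correlation). Here 5 passed when adjusted over the list alone, among them Mmp2 (-0.54, SE 0.12), Col1a1 (-1.46, SE 0.395), Col3a1 (-1.02, SE 0.303) and Postn (-0.45, SE 0.143). Glucocorticoid response (median -0.34, adjusted p = 0.00121) and lacrimal and salivary genes (-0.20, adjusted p = 0.0198) were lower in adult males, both at adjusted p = 0.481 with an estimated correlation. Basal keratinocyte and adipocyte (adjusted p = 0.0233 for both) and secretory pathway genes (adjusted p = 0.0337) were lower and hair follicle genes higher (adjusted p = 0.0489), each at adjusted p = 0.573 with an estimated correlation. Over all genes 0 of 24470 passed with limma in either sex, with 1802 at an unadjusted p under 0.05 in females and 1021 in males. The smallest p fell in females on Cttn (0.60, SE 0.0934) and Col4a2 (-1.07, SE 0.173), both at adjusted p = 0.436. Next came Stab1 (-0.57), Col6a3 and the serine synthesis enzyme Phgdh (-0.54), all at adjusted p = 0.474. In males it fell on Dgat2, which makes triglycerides (-1.08, SE 0.165, adjusted p = 0.238), Cd63 (-0.54, SE 0.114), Xlr3c (0.70), Mfsd10 (-0.38) and Szrd1 (-0.40), the latter 4 at adjusted p = 0.972. Aox4 was at 0.56 (SE 0.434, adjusted p = 0.972) in males and at -0.0061 (SE 0.485, adjusted p = 1.00) in females, a sign that turned in 6 of 31 alternatives, and the value in males was 0.14 without young male 4. With array weights 538 genes passed in females, and without young female 3 it was 1 gene. Without adult male 3, 1 gene passed in males. For sex by age 0 passed with limma (648 at an unadjusted p under 0.05). The matrix list was higher in the male than in the female age effect (19 of 23 positive, median 0.28, adjusted p = 0.00342) and the lacrimal and salivary list lower (18 of 22 negative, median -0.21, adjusted p = 0.0179), both at adjusted p = 0.934 with an estimated correlation. There Aox4 was at 0.57 (SE 0.651), turning to -0.11 with all mice and the pair as a block. Ccl21c (0.91, SE 0.230), Mcm2 (0.92, SE 0.241), Tmbim4 (-0.71), Clcn5 (0.64) and Slxl1 (-0.48) came first, all at adjusted p = 0.974.

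**Figure D4:**
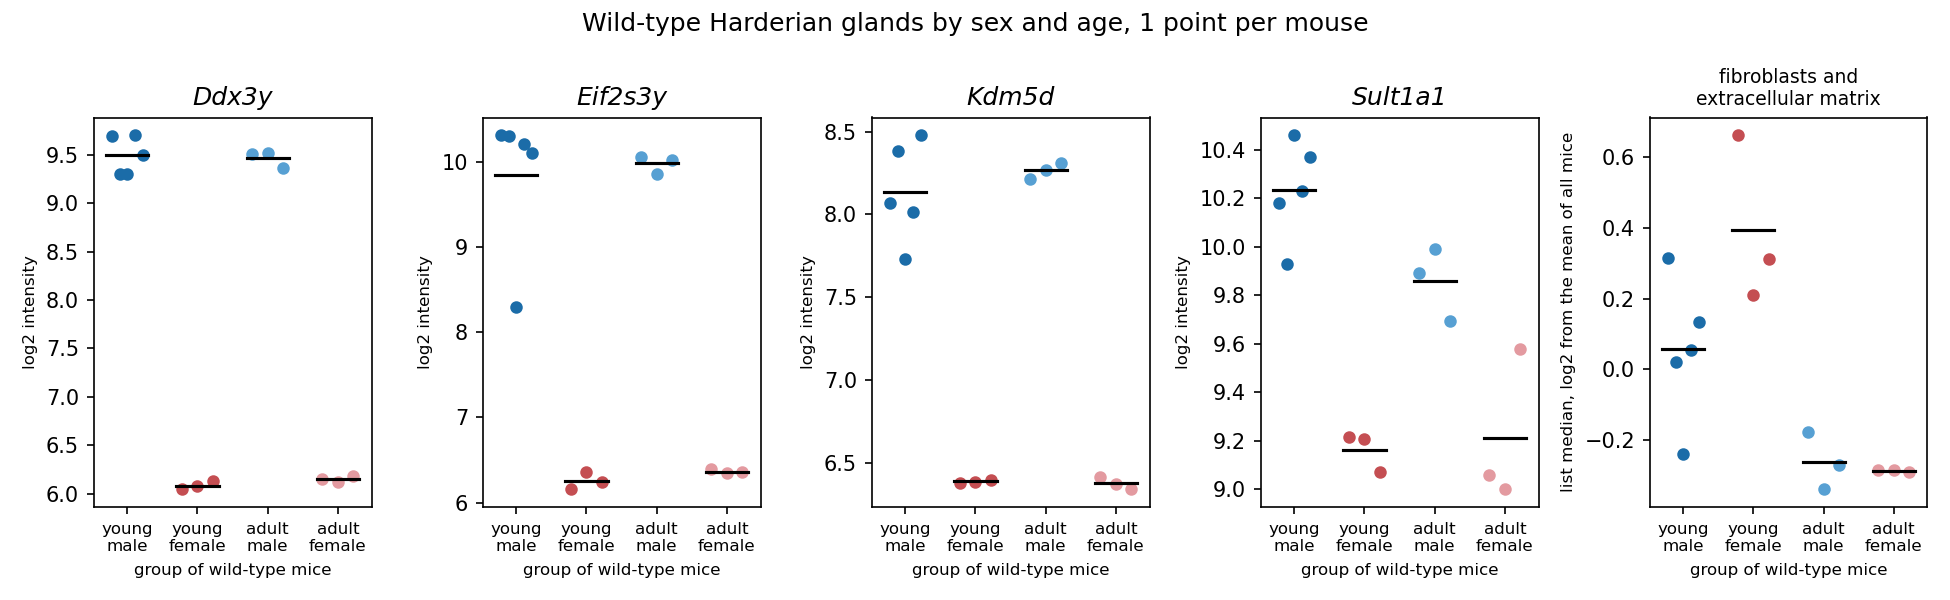
Log2 intensity of Ddx3y, Eif2s3y, Kdm5d and Sult1a1 and the median of the extracellular matrix list relative to all mice (y axes) for each wild-type mouse (points) by group, with group means as black lines. Ddx3y lies between 9.30 and 9.70 in males and between 6.04 and 6.18 in females, and Eif2s3y reads 8.29 in 1 young male.

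In skin the labelled knockout and the labelled wild type were compared in 4 pairs of adult females, and every direction given here depends on those labels. Aox4 was higher in the labelled knockout in 4 of 4 pairs (0.39, 0.77, 0.93 and 0.66), by 0.69 on average (SE 0.156, SD 0.23, adjusted p = 0.329; exact two-sided sign test p = 0.125, the smallest that 4 pairs allow). The probe was above background in 4 of 4 labelled knockout channels and in 0 of 4 labelled wild-type channels, so the size of the difference depends on the background. It was 0.48 without background subtraction, 2.43 with the Feature Extraction signals and 2.25 with the authors' deposited values. The direction is against that of a knockout and against the Harderian gland, so the names of the genotypes are kept as labelled. With limma 0 of 18315 genes passed (2438 at an unadjusted p under 0.05). The smallest p fell on the transcription cofactor Zmiz1 (1.86, SE 0.256), the ephrin Efnb1 (1.81, SE 0.258), the histone gene H2ac13 (1.61, SE 0.207), the cell cycle factor E2f2 (1.57, SE 0.239) and the Wnt inhibitor Frzb (-0.91, SE 0.139), all at adjusted p = 0.329. Leaving out pair 2 gave 196 genes, Zmiz1 and Efnb1 among them (adjusted p = 0.0315 and 0.0366).

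Gene lists in skin, as labelled, differed from pair to pair. Hair follicle genes were higher in the labelled knockout (33 of 34 positive, median 0.70, adjusted p = 0.00130), and so were proliferation genes (33 of 33 positive, median 0.42, adjusted p = 2.72e-05), both at adjusted p = 0.975 with an estimated correlation. Cholesterol synthesis (21 of 23 positive, median 0.28, adjusted p = 0.0189) and melanocyte genes (12 of 13 positive, median 0.48, adjusted p = 0.0463) were higher and muscle genes lower (33 of 34 negative, median -0.94, adjusted p = 6.32e-08), all at adjusted p = 0.975 with an estimated correlation. The pair medians were 0.74, 2.55, -0.35 and -0.56 for hair follicle genes, 0.64, 1.45, -0.16 and -0.07 for proliferation, 0.69, 1.61, -0.16 and -0.02 for melanocytes and 0.16, -2.16, -1.63 and 0.12 for muscle. The signs of the hair follicle, proliferation and melanocyte lists followed the dye order, with the labelled knockout in Cy5 in pairs 1 and 2 and in Cy3 in pairs 3 and 4, and muscle genes were lower in pairs 2 and 3. Foxn1, a hair shaft regulator, read 0.67 (SE 0.307), Mcm5 0.75 (SE 0.210), the sterol regulator Srebf2 0.55 (SE 0.159), the pigment enzyme Tyrp1 0.95 (SE 0.240), Pmel 1.45 (SE 0.411) and Myl3 -1.42 (SE 0.362). Direct retinoic acid targets did not pass (median 0.19, adjusted p = 0.567), with the receptor Rarg at 1.29 (SE 0.324), nor did retinoid metabolism, with Aldh1a1 at -0.88 (SE 0.262). Adjusted over the list alone, Aox4 and its paralog Aox1 (-0.74, SE 0.190), lower in the labelled knockout, passed in the molybdenum list (p = 0.0417 for each). Without pair 2 the lists past the threshold numbered 2, both lower, and without pair 4 they numbered 9. Median centring moved the median of all genes in skin by 0.17.

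The Harderian gland and skin were set side by side over 14617 genes measured in both. Of the Harderian gland neighbours of Aox4, skin as labelled gave Map2 -0.30 (SE 0.202), Bzw1 -0.29 (SE 0.322, on another probe than in the gland, whose own probe gave 0.35, SE 0.281), Ppil3 0.26 (SE 0.166), Mfsd9 -0.084 (SE 0.158), Il1r1 0.30 (SE 0.245) and Slc40a1 0.058 (SE 0.256). Of 6 genes higher and 6 lower in the Harderian gland past the adjusted threshold, 0 were shared with skin by limma, where 0 passed. At an unadjusted p under 0.01 in both tissues, 8 genes were higher in both against 6.41 by chance (Fisher's exact two-sided p = 0.540) and 4 were lower in both against 3.13 (p = 0.557). Across genes, which are not independent replicates, the log2 ratios of both tissues correlated at -0.0023 (Pearson) and -0.063 (Spearman). Over 831 genes with an unadjusted p under 0.01 in the Harderian gland and not within 20 Mb of Aox4, these were -0.132 and -0.187, with 58.7% of opposite sign against 52.95% over all genes. For the 725 of them with the same probe in both tissues they were -0.116 and -0.172. Within 10 Mb of Aox4, 24 of 94 genes had an unadjusted p under 0.05 in skin (25.5% against 13.2% elsewhere, Fisher's exact two-sided p = 0.00122), and within 5 Mb 11 of 60 (p = 0.252).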

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

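The test of DNA linked to the knockout was set before the results were seen, while the tests of a variant under a probe, of a response wherever a gene lies, of crossed skin labels, of dye or slide, of dim probes, of a shared source of signal and of a single pair were chosen only after the result was seen.

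In 56 groups of values looked through for a sample far from the others, 8 held one, where chance gives 2.8 (5% of groups). In young male wild-type Harderian glands Aox4 had a log2 level of 11.09 in mouse 4, against 13.03 to 13.63 in the other 4 mice. The Y-linked Eif2s3y read 8.29 in young male wild-type mouse 3 against 10.10 to 10.31 in the other 4, while Ddx3y and Kdm5d of that mouse were at male levels. Of the log2 ratio medians per young male pair, muscle genes read 1.42 in pair 3 (others -0.75 to -0.44) and cholesterol synthesis 0.13 in pair 3 (others -0.098 to -0.040). Endoplasmic reticulum stress genes read -0.099 in pair 4 (others 0.028 to 0.059) and immediate early genes -0.18 in pair 4 (others 0.0019 to 0.028). Basal and suprabasal keratinocyte genes read -0.17 in pair 2 (others -0.040 to -0.00065). In skin the median net green signal was 100.1 on the array of pair 3, against 57.9 to 62.1 on the other 3.

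Genes that passed over all Harderian gland groups lay near Aox4 far more often than elsewhere. The odds ratio of 127 within 20 Mb (Fisher's exact two-sided p = 9.1e-12) is this pattern itself and no separate test. A response to the loss of Aox4 that does not depend on where a gene lies would not by itself give it. Such a response stays open for the 6 genes that passed elsewhere. A sequence variant under 1 probe is argued against as the whole cause for 3 of the 7 genes near Aox4, Bzw1 and Mfsd9 among them, since 6 of 6 other bright probes of these changed the same way. The other bright probe of Mfsd9 read 0.22 against 0.84 on the probe used, so a part that belongs to 1 probe stays open there. For the other 4 genes, which have no other bright probe, such a variant stays open. DNA of another strain linked to the knockout may account for the pattern, as the odds ratio of 67.0 within 5 Mb (exact p = 0.000582) is of the kind it needs, but that value rests on 2 of 68 genes, and at an unadjusted p under 0.01 and 0.05 the odds ratios within 5 Mb were 1.27 and 1.33 (exact p = 0.562 and 0.379) and within 20 Mb 2.30 and 1.79 (exact p = 0.000689 and 0.000498). The labels name 1 strain for all mice, no genotypes were read, and an effect of the altered Aox4 gene on its neighbours through the chromosome was not tested.

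In skin Aox4 was higher in the labelled knockout (mean 0.69, 4 of 4 pairs) where every Harderian gland pair was lower (-4.67 to -2.43), and this difference between tissues was not tested. Dye or slide is argued against, since the mean ratio was 0.579 in 1 dye order and 0.792 in the other. A shift of dim probes could not be fully tested, since loess had centred the ratios at each brightness. The median ratio of genes of that brightness, 0.0076, was thus held near 0. After loess 1.13% of these 2477 genes (28 genes) differed as much as Aox4. Loess does not change the calls above background, and these went 1 way. There 72 probes were above background in all 4 labelled knockout channels and in 0 labelled wild-type ones, against 0 the other way. A shift stays open for those calls. Whether the skin channel labels are crossed cannot be told apart from the labels being right: the test needs the 7 called neighbours of Aox4 to act in skin as in the Harderian gland, and the slope of their skin ratios on the gland ratios was 0.0576 (SE 0.130), or 0.114 (SE 0.129) with Bzw1 read on the gland's own probe, near neither sign of the gland effect. A transcript in skin that the knockout leaves or alters, and where the probe lies in the gene, were not tested.

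The 195 genes higher in young males may share a source of signal rather than respond one by one. Probes that share 1 source of signal are a candidate explanation, as the ratios of 191 of these genes correlated at a median of 0.646 over the 9 pairs of the other groups, against 0.0335 in the highest of 100 random sets. A single pair is argued against as the whole cause: 195 genes chosen without a pair had medians of 0.634, 0.734, 0.872, 0.813 and 0.127 in that pair, for pairs 1 to 5. They exceeded the highest of 100 random sets in 5 of 5 pairs. Genes drawn at random do not move together as these do, so that excess does not measure chance. The count past the threshold fell to 1 without pair 4. The median ratio of the called genes was 0.751 without pair 4 and 0.787 with all pairs, though these genes were called with pair 4 included. What the shared source is was not tested, and a response to the knockout that is itself shared by these genes stays open, as does one that depends on age or sex, where 0 genes passed by limma for either interaction (2438 and 2679 at an unadjusted p under 0.05).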

How the results depend on the processing

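The filter against negative controls, both left-out sets (the array with scattered controls, alone and with the widest pair) and the gland's own probe for the neighbours of Aox4 in skin were chosen only after the data were seen, while the other alternatives were set earlier.

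Under alternatives 437 values of comparisons were taken: counts, the change of Aox4 and the odds ratios near it. Of these 350 stayed the same and 87 counts moved by more than 1.5 times. A count stayed the same if it lay within 1.5 times, and the other values if they kept their direction and their side of the threshold. Counts that were 0 and remained 0 are among the 350, so that number does not measure how stable the larger counts were. For named genes past the threshold, 871 of 1131 values stayed past it and 260 did not, with 0 reversed. For those not past it, 1375 of 1408 stayed so, 25 passed and 8 reversed. Aox4 and Map2 over all Harderian gland groups passed in all 31 alternatives (Aox4 from -3.26 to -3.08), and Aox4 in skin stayed higher in the labelled knockout in all 16 (0.48 to 2.43). Signal over background limits that last value and the sex differences of Y-linked genes, where female arrays above background were 0 of 6 at either age for Ddx3y, 2 of 6 in young (3.19 to 6.76) and 3 of 6 in adult mice (3.29 to 6.35) for Eif2s3y and 2 of 6 in adults for Uty (1.07 to 3.69). Scan date as a block could not be fitted in skin, which has 1 date. Except where stated, the cause was not tested.

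The number of lists past the threshold over all groups (9) became 0 with an estimated correlation, 1 by fry and 4 with the Feature Extraction signals. The 1 list by fry was that of the molybdenum flavoenzymes, which holds Aox4 itself and was not among the 9. In skin (5) the number became 0 with an estimated correlation and 0 by fry. Genes shared by both tissues were 0 when adjusted and 12 at an unadjusted p under 0.01. With every probe tested, so that a gene counts more than once, 34 passed over all groups (14 otherwise), 1050 in young females (250), 2 in adult males (1), 2 in adult females (1), and between wild-type sexes 9 in young (4) and 7 in adult mice (4). Without a filter on dim probes 138 passed in young females. With only probes well above background in every channel it was 728 in young females and 0 between the sexes at either age, since that filter removes the Y-linked genes (1348 and 419 at an unadjusted p under 0.05). Without background subtraction young males gave 108 (205) and young females 148. The Feature Extraction signals gave 1 in young females and reversed As3mt by age to 0.23 and Aox4 between ages of wild-type females to 0.00071. Quantile normalisation reversed the latter to 0.054. Median centring gave 6 in young females. Over all groups it left 13 genes (10 higher, 3 lower) and 9 lists (4 higher, 5 lower). Without the dye correction young males gave 564 and young females 83. All 30 arrays gave 518 in young females and 2 in adult females. The robust prior gave 121 in young males and 155 in young females. Array weights gave 35 over all groups, 95 in young males, 3 in adult females, 28 between adult wild-type sexes and 538 between ages of wild-type females (0).

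The authors' deposited values gave 2 in young males, 3 in young females and 2 in adult females. Groups fitted on their own pairs, with fewer degrees of freedom, gave 3 in young males, 0 in young females and 0 in adult males (2864 and 1469 at an unadjusted p under 0.05). No replicate block gave 4 over all groups, 0 in young males, 1 in young females, 0 in adult males and 0 in adult females, with 336, 168 and 6 at an unadjusted p under 0.05 where the count was 0. Scan date as a random block gave 8 over all groups and 22 in young females. All mice with the pair as a block gave 9 between young wild-type sexes and reversed Aox4 between ages of wild-type females to 0.46 and in sex by age to -0.11. Leaving out the array with scattered controls and the widest pair gave 33 over all groups, 752 in young females and 1 between ages of wild-type males.

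With each pair left out in turn, the counts ran from 8 to 193 over all groups, 1 to 354 in young males, 3 to 1331 in young females, 1 to 2 in adult males, 1 to 2 in adult females, 0 to 0 by age and 0 to 188 by sex. The lowest were without adult male pair 3, young male pair 4 and young female pair 1, and the highest without young male pair 5 (all groups, young males and by sex) and young female pair 3. Between wild-type mice they ran from 3 to 7 (young sexes), 2 to 4 (adult sexes), 0 to 1 (ages, males), 0 to 1 (ages, females) and 0 to 0 (sex by age). In skin they ran from 0 to 196, the latter without pair 2. Lists ran from 4 (without young female pair 1) to 10 over all groups, and in skin from 2 (without pair 2) to 9 (without pair 4). Aox4 between ages of wild-type females ran from -0.23 (without adult female 1) to 0.19, and reversed to 0.19 without young female 3, 0.068 without adult female 2 and 0.15 without adult female 3. Without young male 4, Aox4 read -0.58 between young wild-type sexes (-1.0 otherwise) and 0.14 between ages of wild-type males (0.56). In groups of 3 pairs the 2 that remain were assumed to vary like the other groups.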

Other observations

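The comparison of mice by weeks of age was chosen only after the result was seen, and the splits of the samples in the other 13 comparisons were set before.

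Among young mice, 9 of 35 lists passed by camera between 6 and 5 weeks of age in wild type and 7 in knockout, and 0 with an estimated correlation. In wild-type Harderian glands 32 of 33 proliferation genes were lower in 4 mice of 6 weeks than in 4 mice of 5 weeks, with sex as a term (median -0.37, camera adjusted p = 2.42e-20, fry adjusted p = 0.0116, and adjusted p = 0.130 with an estimated correlation). Adjusted over the list alone 24 passed, among them the mitotic genes Birc5 (-0.81, SE 0.116) and Ube2c (-0.91) and the nucleotide enzyme Rrm2 (-0.84, SE 0.140). Muscle genes were lower too, with 33 of 34 negative (median -1.29, camera adjusted p = 1.25e-30, fry adjusted p = 0.0551, and adjusted p = 0.310 with an estimated correlation), and adjusted over the list alone 31 passed as lower and 1 as higher, with Pvalb at -1.39 and Ttn at -1.70. Per mouse, the median of the proliferation list was 0.21 (SD 0.089, n = 4) at 5 weeks and -0.21 (SD 0.070, n = 4) at 6 weeks, and for muscle it was 0.59 (SD 0.309) and -0.56 (SD 0.443) (exact two-sided permutation p = 0.0286 for each, the smallest that 4 against 4 allow). All permutation tests of weeks were run only on lists that camera had called in either genotype, on the same mice. They left sex out and were not adjusted over lists, so they are no separate support. In knockout mice the proliferation list read -0.32 (25 of 33 negative) and the muscle list -0.54 (30 of 34 negative). Both passed by camera (adjusted p = 0.000138 for each, and adjusted p = 0.676 with an estimated correlation), but the medians per mouse gave exact two-sided permutation p = 0.229 and 0.457. Hair follicle genes were higher at 6 weeks in both genotypes (26 of 32 positive in each, camera adjusted p = 0.0129 in wild type and 0.000442 in knockout, and adjusted p = 0.310 and 0.654 with an estimated correlation). Their medians per mouse were -0.044 at 5 and 0.066 at 6 weeks in wild type and -0.092 and 0.052 in knockout (exact two-sided permutation p = 0.0286 for each). The wild type and knockout of a pair shared arrays and age, and across genes their deviations correlated at 0.554 to 0.887 in the young pairs. The 2 genotypes are therefore not independent of each other. Scan date was not fitted here, and over all groups wild-type levels correlated at 0.447 within a scan date. Also lower at 6 weeks in wild type were matrix (median -0.30, camera adjusted p = 0.00223), adipocyte (-0.17, 0.00683), immediate early (-0.13, 0.00683), acute phase (-0.12, 0.00897), interferon (-0.084, 0.0178) and glucocorticoid response genes (-0.21, 0.0340), with exact two-sided permutation p of 0.0857 to 0.257. Immune cell genes were higher at 6 weeks in knockout (median 0.11, camera adjusted p = 0.00486, exact two-sided permutation p = 0.0286) and leaned the same way in wild type (24 of 31 positive, median 0.078, camera adjusted p = 0.0926, exact two-sided permutation p = 0.143). Immediate early genes did not pass by camera in knockout (adjusted p = 0.0842), but their medians per mouse were 0.036 at 5 and -0.041 at 6 weeks (exact two-sided permutation p = 0.0286). In knockout fatty acid oxidation genes (0.19, 0.00431) were higher and matrix (-0.10, 0.0412) and glucocorticoid response genes (-0.34, 0.0412) lower, with exact two-sided permutation p of 0.0857, 0.286 and 0.114. Over all genes 0 passed by limma (3476 at an unadjusted p under 0.05 in wild type, 2927 in knockout).

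Single members of lists that did not pass as a whole moved over all Harderian gland groups when adjusted over the list alone. Of the sebaceous gland list (adjusted p = 0.555), the melanocortin receptor Mc5r read 0.32 (SE 0.0704) and the fatty acid elongase Elovl3 0.20 (SE 0.0486). S100a8, an alarmin of neutrophils, read 0.30 (SE 0.0629) and belongs to both the wounded epidermis (adjusted p = 0.308) and the acute phase list (0.555). Kit read -0.23 (SE 0.0480) in the melanocyte list (0.981), the myelin protein Mbp -0.13 (SE 0.0293) in the nerve list (0.308), Cald1 0.26 (SE 0.0698) in the smooth muscle list (0.597), the ion cotransporter Slc12a2 -0.19 (SE 0.0422) in the lacrimal and salivary list (0.981) and Eif2s3x -0.13 (SE 0.0323) in the sex chromosome list (0.962). All of these had adjusted p of 0.0986 or more over all genes, and 0 of them passed by limma. The other lists gave adjusted p = 0.103 (hair follicle), 0.0947 (interferon), 0.211 (androgen and estrogen signalling), 0.605 (endothelium and blood), 0.716 (circadian clock), 0.762 (immune cells), 0.762 (xenobiotic metabolism), 0.894 (heme synthesis), 0.894 (secreted proteins), 0.894 (glucocorticoid response), 0.910 (secretory pathway), 0.962 (retina and lens), 0.967 (adipocytes) and 0.991 (fatty acid synthesis).

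Splits of the same samples were counted for each comparison. Over all Harderian gland groups chance can be excluded for the count as a whole. Of 100 drawn exchanges of knockout and wild type within pairs (8192 possible), 1 gave as many genes, the real one with 14. The highest other gave 1. The 14 hold the deleted gene Aox4 and 7 genes within 20 Mb of it. The 6 genes elsewhere were not split on their own, so chance is not excluded for them. The splits are too few for a share under 0.05 in young males (1 of 16 splits as large, real 205, highest other 0), young females (1 of 4, 250 and 0), adult males (1 of 4, 1 and 0), adult females (1 of 4, 1 and 0), skin as labelled (8 of 8, 0 and 0), the sexes of adult wild-type mice (1 of 10, 4 and 0) and the ages of wild-type females (10 of 10, 0 and 1). Where 0 genes passed by limma every split is as large by construction, so the count decides nothing on chance, neither in skin and the ages of wild-type females above nor for the genotype effect by age (100 of 100, 0 and 0) and by sex (100 of 100, 0 and 0). The same holds for the ages of wild-type males (56 of 56, 0 and 0), sex by age (100 of 100, 0 and 1) and the weeks of age of young wild-type mice (35 of 35, 0 and 260).

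Between the sexes of young wild-type mice chance cannot be excluded by the count alone, as 3 of 56 splits gave as many genes as the real one with 4, and the highest other gave 362. That split sets apart young male 4 and young females 1 and 2, all of 5 weeks, and another split with 205 calls sets apart young males 2 and 5 and young female 3, all of 6 weeks. These counts point to a structure of the samples whose source is not known. The division by weeks of age itself gave 0 genes by limma (3476 at an unadjusted p under 0.05), and young male 1, also of 5 weeks, is outside the first set. Young females 1 and 2 also share their scan dates. With scan date as a block 3 genes passed between the sexes. The real split calls the Y-linked Ddx3y, Eif2s3y and Kdm5d.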
